A study of Gallus gallus with 6 samples.

How the data were processed

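Leukocytes were taken from the interface of a density gradient loaded with wing-vein blood, and total RNA was labelled with Cy3 and hybridised to a 1-colour chicken oligonucleotide array, per the labels' protocols. There were 6 arrays, 3 labelled female and 3 labelled male, grouped by the labels alone. The age unit, months, comes from the series' design text.

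Each scanner table held the spot intensity deposited by the authors, as read by Agilent Feature Extraction 11.5.1.1 per the file headers; its processed signal is background-subtracted with spatial detrending within an array and is not scaled between arrays. The array's grid names the chicken build galGal3, per the file headers. The deposited flags mark spots well above background, saturated spots and outliers. The authors' deposited matrix held the same processed intensity times 1 factor per array, between 2.10 and 2.31, linear and not centred. The column medians of that matrix were 318, 313 and 291 in the libraries labelled female and 286, 292 and 301 in those labelled male; the target of the scaling is not given in the sources used here. The 75th percentile of the processed intensity lay between 873 and 983 over the arrays, and 3 to 12 flagged outlier spots per array were left out.

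From these values, log2 of the processed signal was taken and each array's 75th percentile over non-control spots was subtracted. Spots of a probe were averaged. A probe was kept if it was well above background on at least 3 of 6 arrays, which 35141 of 43603 probes were; 11 of them lacked a value on an array and were not tested. A gene was represented by its kept probe with the highest mean, and a probe with no gene name stayed a feature of its own. Gene names and chromosomes came only from RefSeq accessions matched without version to a RefSeq gene table of the assembly bGalGal1.mat.broiler.GRCg7b, which is not the array's build, so no coordinates are given. It matched 11935 probes to 5382 genes, 222 of them on Z and 9 on W. The other 31668 probes, 14692 of them with an Ensembl transcript name, have no name here.

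The labelled sexes were compared with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all features) in R 4.3.3, with the difference coded male minus female and an adjusted p threshold of 0.05. Features that differed by at least 2-fold in the same direction in all 9 pairs of 1 male and 1 female array were counted without a test, since the series' design text speaks of comparing the triplets by brute force. The Z shift is the median difference of Z genes less that of autosomal genes. It was tested with limma's camera at a preset correlation of 0.01 and, per array, with a two-sided exact permutation test. The 20 gene lists, the tests, the samples in each and the rule for named genes were fixed before the data were examined. Lists with at least 5 measured members were tested with camera. Counts over a list alone use adjustment within the list. A feature not well above background in any library of a group is given as at least N-fold: the bright group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest value well above background.

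Named genes were up to 8 W-linked genes and 8 Z gametologs with the smallest p, up to 8 per direction past the threshold without overlap and 6 such autosomal ones (none passed), up to 4 members per list with the smallest p, and the 5 with the largest smallest pairwise difference per direction. For the last part the 5 with a gene name per direction were added. One gene that this rule takes is not reported here.

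The fits were tested on simulated data for the 3 against 3 comparison of 29509 features, with the measured spread and 200 changed features. Of 50 features changed 1.5-fold, 0 were recovered, of 50 changed 2-fold 8.0%, of 50 changed 4-fold 78.0% and of 50 changed 8-fold 100%. A Z shift of 0.5 log2 was recovered as 0.55. All these changes were put in every male-labelled library and in no female-labelled one. The recovered shares thus do not hold for a difference that some libraries carry against their labels. Alternatives covered background correction and scaling, probe filters and summaries, test settings, the replicate number as a block, and left-out libraries. The normexp alternative used the median spot signal with its local background (offset 50), because the mean spot signal planned for it was not among the columns used here. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.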

Results

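Blood leukocytes of chickens aged 1 to 2 months were profiled in 6 samples, 3 labelled female and 3 labelled male, with 1 array each. The stated question was which genes differ between the sexes in these cells. In birds, males carry 2 Z chromosomes and females carry 1 Z and 1 W. Each array held 43803 non-control spots, of which 79.0% to 83.1% were well above background, and none was saturated. The labels number the samples within each sex but do not say whether each came from a separate bird. The limma p-values of single genes thus measure only the spread between these samples. Camera instead compares the genes of a set with the other genes, so its p-value rests on the correlation between genes taken for it. The number of arrays limits the precision of every value. All 3 libraries labelled female lay on 1 slide and all 3 labelled male on the other, so slide and label cannot be told apart.

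HINTW, a W-linked member of the HINT family, checks the sex labels, and 2 of the 6 libraries went against them. On its brightest probe the libraries labelled female 1, 2 and 3 read 6.61, 6.47 and 4.65 (log2, relative to the array's 75th percentile), and the libraries labelled male 1, 2 and 3 read 4.58, 4.48 and 6.99. The library labelled female 3 thus lay with those labelled male 1 and 2, and the library labelled male 3 with those labelled female 1 and 2. The brightest probe showed the smallest difference of the gene's 8 probes. On the 5 HINTW probes well above background in all 6 libraries, the libraries labelled female 1 and 2 were 2.01 to 10.88 log2 above those labelled male 1 and 2. On the same probes the library labelled female 3 was 1.89 to 10.89 log2 below the mean of female 1 and 2, and the library labelled male 3 was 2.46 to 11.32 log2 above the mean of male 1 and 2. On the other 3 probes the libraries labelled male 1 and 2 were not well above background. LOC100857579, a second W-linked gene with the synonym HINTWL2, read 4.87, 4.56 and 2.41 in the libraries labelled female and 2.45, 2.25 and 5.20 in those labelled male.

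Z-linked genes ran opposite to HINTW in every library. The median of the 198 measured Z genes, less that of the 4647 autosomal genes, was -0.28, -0.26 and 0.28 log2 in the libraries labelled female 1, 2 and 3, and 0.27, 0.26 and -0.26 log2 in those labelled male 1, 2 and 3. Every direction given below is between the labels as deposited, with the libraries labelled female 3 and male 3 in their stated groups. Values without these 2 libraries are given beside each main count, and that alternative was chosen after the data were seen. The choice rested on the HINTW and Z values above. The W and Z results without these libraries thus follow in part from it, and their p-values are no separate evidence.

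**Figure D1:**
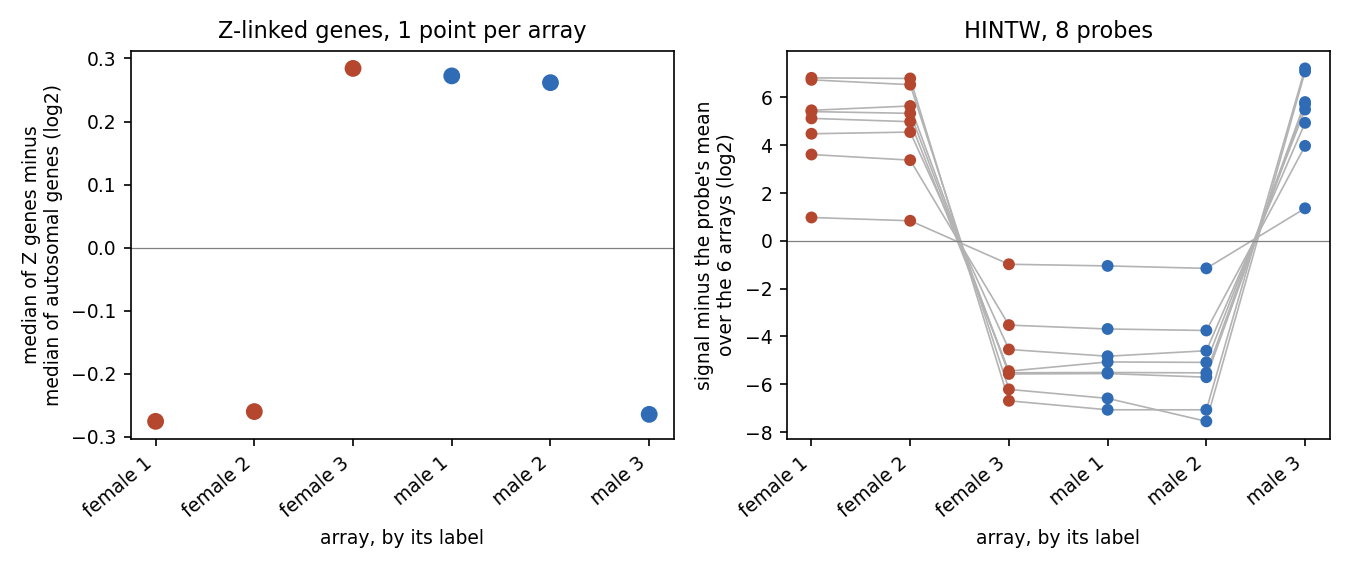
Left, the median log2 deviation of Z-linked genes less that of autosomal genes (y axis) in each array by its label (x axis), 1 point per array; right, the log2 signal of the 8 HINTW probes, each less its own mean over the 6 arrays (y axis), with a grey line joining the points of a probe. Red points are libraries labelled female and blue points libraries labelled male; the library labelled female 3 sits at 0.28 on the left, beside those labelled male 1 and 2, and the library labelled male 3 at -0.26.

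W-linked genes did not separate the labelled sexes. None of the 9 measured W genes passed (limma, adjusted p threshold 0.05), and their unadjusted p-values started at 0.211. With each of their 35 kept probes tested separately none passed either. HINTW was 0.56 log2 lower in the libraries labelled male than in those labelled female (SE 0.83, limma adjusted p = 0.948), with means of 5.35 ± 1.42 and 5.91 ± 1.09 (SD, n = 3 each). LOC100857579 gave a male minus female difference of -0.65 log2 (SE 0.99). The male minus female difference was -0.21 log2 for UBAP2L2, 0.13 for HNRNPKL, -0.15 for MBD2, 0.10 for SPIN1L, -0.09 for SMAD7B and -0.04 for ENS-1, and none of them passed. These values come from each gene's brightest probe. Each of these probes was well above background in all 6 libraries, though males carry no W chromosome. Their signal thus need not come from the W gene alone, and its source was not tested. Another UBAP2L2 probe read -1.95, -2.18 and -3.12 in the libraries labelled female and -3.64, -3.44 and -2.44 in those labelled male. Another SPIN1L probe gave a difference of -0.25 log2, and the mean of all kept SPIN1L probes gave -0.07. Without the libraries labelled female 3 and male 3, 1 W gene passed: HINTW, at -2.01 log2 (limma adjusted p = 0.0406, the lowest of its 18 alternatives, which reached 1.0), while LOC100857579 at -2.37 log2 did not (limma adjusted p = 0.0508). Both values come from the brightest probe of each gene, which differed least; the other 2 LOC100857579 probes were well above background in the libraries labelled female 1, female 2 and male 3 and in none of the others.

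Z-linked genes were higher in the libraries labelled male by a median of 0.20 log2, against 0.03 for autosomal genes, a shift of 0.17 log2. Of the 198 Z genes, 158 (79.8%) were higher in the male-labelled mean, against 56.4% of autosomal genes, and no Z gene passed on its own. The shift passed limma's camera with a preset correlation of 0.01 (p = 2.088e-06). It did not pass with the estimated correlation, which was 0.38 (camera p = 0.401). Per library, the Z value averaged 0.09 ± 0.31 in the male-labelled and -0.08 ± 0.32 log2 in the female-labelled group (SD, n = 3 each; two-sided exact permutation p = 0.90, where the smallest possible p is 0.10). Without the libraries labelled female 3 and male 3 the shift was 0.56 log2, or 1.47-fold, with 167 of the Z genes (84.3%) higher in the male-labelled mean (camera p = 1.787e-23, and 0.0194 with an estimated correlation).

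Of 10 measured Z partners of W genes, 9 were higher in both libraries labelled male 1 and 2 than in those labelled female 1 and 2, and on 7 of these 9 both libraries numbered 3 lay on the other side of the midpoint; SMAD2, CHD1 and DDX4 were the exceptions. HINT2, listed with the synonym HINT1Z, read 3.49, 3.57 and 4.81 in the libraries labelled female and 4.83, 4.66 and 3.73 in those labelled male. Its male minus female difference was 0.45 log2 (SE 0.45), and 1.21 log2 without the libraries labelled female 3 and male 3. ATP5F1AZ, a subunit of the mitochondrial ATP synthase, differed by 0.44 log2 (SE 0.35), and by 1.02 without those libraries. The transcription coactivator SUB1 differed by 0.34 log2 (SE 0.38), and by 0.97 without them. SMAD2 differed by 0.24, SPIN1 by 0.23, UBAP2 by 0.20 and UBE2R2 by 0.18 log2, while the germ cell helicase DDX4 was at -0.50 log2. None of the 8 genes given with a difference passed with all 6 libraries, nor without the pair (limma, adjusted p threshold 0.05).

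RGS16, a regulator of G-protein signalling on chromosome 8, showed the widest gap of any named gene between the labelled sexes over all 9 pairs of 1 male-labelled and 1 female-labelled library. It read 2.50, 2.22 and 2.78 log2 in the libraries labelled female and -2.42, -4.98 and -4.68 in those labelled male, so that the smallest of the 9 differences was 4.64 log2. The mean male minus female difference was -6.53 log2 (SE 0.67, 92.5-fold lower), with a limma adjusted p of 0.247. A second RGS16 probe, also well above background in all 6 libraries, differed by only -0.99 log2, so the probes of this gene disagreed in size. Of 29509 features tested (4859 named genes and 24650 unnamed probes), 25 differed by at least 2-fold in the same direction in all 9 pairs. Of these, 15 were higher and 10 lower in the male-labelled libraries, and RGS16 was the only one with a gene name. The count takes values as read, also those under the lowest value well above background. Some of the 25 are thus not measurably 2-fold. With probes well above background on all 6 arrays 14 were left, 9 higher and 5 lower. After normexp background correction 8 features were left, 4 in each direction, and without the libraries labelled female 3 and male 3 there were 594, 202 higher and 392 lower. Among unnamed features, ENSGALT00000045424 was at least 41.2-fold lower in the male-labelled libraries, where it was not well above background, and A_87_P086621 at least 21.1-fold lower. ENSGALT00000014678 was at least 2.02-fold higher in the male-labelled libraries and ENSGALT00000017478 at least 1.41-fold, with the female-labelled libraries not well above background. The limma adjusted p of these 4 was 0.104 to 0.149.

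Other named genes with a large smallest pairwise difference stayed under 2-fold in at least 1 pair. OLFM1 was 1.59 log2 higher in the male-labelled mean (SE 0.25), MPZL2 1.49 (SE 0.29) and the histone gene HIST1H111L 1.19 (SE 0.26). GPATCH11 was 1.00 (SE 0.17) and XK, a member of the erythroid list, 1.77 log2 higher (SE 0.50). OLFM1 and XK were each well above background in 1 of the 3 female-labelled libraries. CNGA3, well above background in 1 of the 3 male-labelled libraries, was at -1.09 log2 (SE 0.20) and C4orf33 at -0.94 (SE 0.16). SMYD1, a muscle histone methyltransferase, was at least 1.62-fold lower in the male-labelled libraries, where it was not well above background. None of these 8 passed (limma adjusted p from 0.87 to 0.948).

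No gene passed between the labelled sexes over all features. With limma, 0 of 29509 features had an adjusted p under 0.05, and the lowest was 0.104. At an unadjusted p under 0.05 there were 1123 features (3.81%), 524 higher and 599 lower in the male-labelled libraries; without those labelled female 3 and male 3 there were 6374 (21.6%), 2597 higher and 3777 lower. With all 6 libraries the share that were higher was 46.7%, and it was 58.1% after normexp background correction, 57.5% with median scaling, 51.8% after quantile normalization, 40.8% with the deposited matrix values and 35.7% with scaling on autosomal probes.

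Without the libraries labelled female 3 and male 3, 85 features passed in limma, 18 higher and 67 lower in the male-labelled libraries, and 594 differed by at least 2-fold in all pairs left. Of the 85, 76 had no gene name and 9 did; these 9 are named after their values were seen. On the Z chromosome, AVD, the egg-white protein avidin, was 2.97 log2 higher in the libraries labelled male 1 and 2, and the forkhead gene FOXD1 was at -2.46 log2. CALB1, a calcium-binding protein on chromosome 2, was at -3.43 log2 and read -2.59, -2.42 and -5.89 in the libraries labelled female and -5.98, -5.90 and -2.81 in those labelled male. FLNA, which encodes filamin A, was at -2.54 log2 and the receptor tyrosine kinase gene ERBB3 at -1.90. LRRC17 was at -4.91, PLA2G4F at -3.21 and SEMA3D at -2.10 log2. Each was well above background in only 2 of the libraries labelled female and 1 labelled male. SEMA3D read -6.70, -6.87 and -6.08 in the libraries labelled female and -8.80, -8.97 and -5.81 in those labelled male. For SEMA3D the library labelled female 3 thus stayed with those labelled female 1 and 2. HINTW completed the 9.

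Cell cycle genes were higher in the male-labelled mean by a median of 0.42 log2, 22 of 25 by sign, and the list passed limma's camera (adjusted p = 1.789e-10 over 20 lists). With an estimated correlation the list's p was 0.142 (adjusted p = 0.729). The spindle checkpoint genes BUB1 and BUB1B differed by 0.67 (SE 0.15) and 0.71 log2 (SE 0.26), the centromeric histone CENPA by 0.62 (SE 0.19) and the mitotic kinase PLK1 by 0.60 (SE 0.21). The list's mean deviation was 0.52 and 0.31 log2 in the libraries labelled male 1 and 2 and -0.23 in that labelled male 3, against -0.26, -0.15 and -0.20 in those labelled female. No member passed over all features or adjusted over the list alone. The median without the libraries labelled female 3 and male 3 was 0.74 log2, with 18 of 25 passing adjusted over the list alone.

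Cytotoxic cell genes were higher in the male-labelled mean in 6 of 6 members, by a median of 0.99 log2 (camera, limma adjusted p = 0.00105). With an estimated correlation the list's p was 0.152 (adjusted p = 0.729). The chemokine CCL5 differed by 1.98 (SE 0.72), granzyme A (GZMA, Z-linked) by 1.98 (SE 1.03), granulysin (GNLY) by 1.13 (SE 0.59) and Fas ligand (FASLG) by 0.85 log2 (SE 0.46). GZMA read 1.01, 2.54 and 2.74 in the libraries labelled female and 4.59, 5.76 and 1.87 in those labelled male. The list's mean deviation ranged from -1.30 in the library labelled female 1 to 1.66 in that labelled male 2, and was -0.49 in that labelled male 3. No member passed over all features or adjusted over the list alone; without the libraries labelled female 3 and male 3 the median was 1.54 log2, with 3 of 6 passing adjusted over the list alone.

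Cytosolic ribosomal protein genes were higher in the male-labelled mean in 43 of 45 members, by a median of only 0.13 log2 (camera, limma adjusted p = 0.000688). With an estimated correlation the list's p was 0.471 (adjusted p = 0.849). RPL22 differed by 0.32 (SE 0.28), RPS27L by 0.24 (SE 0.14), RPL29 by 0.23 (SE 0.21) and RPL12 by 0.19 log2 (SE 0.18), and the library labelled female 3 had the highest mean deviation, 0.25 log2. B cell markers were higher in 11 of 16, by a median of 0.24 log2 (camera, limma adjusted p = 0.0238). With an estimated correlation the list's p was 0.174 (adjusted p = 0.729). Among them the coactivator POU2AF1 differed by 0.42 (SE 0.22), the receptor TNFRSF13B by 0.72 (SE 0.41) and the transcription factor PAX5, on Z, by 0.36 log2 (SE 0.25). No member of either list passed over all features or adjusted over the list alone. The medians without the libraries labelled female 3 and male 3 were 0.28 log2 for the ribosomal list and 0.30 for B cell markers. Neither list passed without the library labelled female 1 or after quantile normalization, and B cell markers also missed without that labelled male 2, after normexp and without their Z-linked members.

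The other 16 lists did not pass limma's camera. Toll-like receptor genes had a median of 0.27 log2 (adjusted p = 0.135), with TLR1A and TLR1B both at 0.55. Z partners of W genes had a median of 0.22 (adjusted p = 0.279), W-linked gametologs -0.04 (0.877) and Z-linked immune genes 0.0035 log2 (0.50). Erythroid markers had a median of -0.17 log2 (adjusted p = 0.393), with 13 of 16 lower in the male-labelled mean. The Rh-associated glycoprotein RHAG was at -1.69 (SE 0.55), while XK, the member with the smallest p, was at 1.77 log2 (SE 0.50). Inflammatory and immediate early genes had a median of 0.10 (adjusted p = 0.389), with LITAF at 1.08 (SE 0.30), nitric oxide synthase NOS2 at 0.69 (SE 0.23) and SOCS3 at -0.49 log2 (SE 0.20). Monocyte and macrophage markers had a median of 0.18 (adjusted p = 0.450), with the scavenger receptor CD36 at -0.62 and FCER1G at 0.80 log2. MHC and antigen presentation genes had a median of 0.07 and a mean of -0.04 log2 (adjusted p = 0.457); the class I gene BF2 read 3.99 in the library labelled male 2 and 6.43 to 7.56 in the others. T cell markers had a median of -0.05 (0.457), thrombocyte markers -0.13 (0.457), heterophil markers -0.49 (0.877), plasma cell markers 0.03 (0.773) and type I interferon response genes -0.04 log2 (0.784). Heat shock and unfolded protein genes had a median of 0.09 (0.292), sterol synthesis and LDL uptake genes 0.08 (0.457) and sex steroid receptors and response genes -0.05 log2 (0.450). At the preset correlation 8 lists passed instead of 4 without the libraries labelled female 3 and male 3, and 0 with an estimated correlation (lowest adjusted p = 0.731). The 4 added lists and their medians there were Z partners of W genes at 0.64 log2 (limma adjusted p = 1.226e-05), toll-like receptors at 0.42 (0.0246), erythroid markers at -0.63 (0.0268) and Z-linked immune genes at 0.29 (0.0308).

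**Figure D2:**
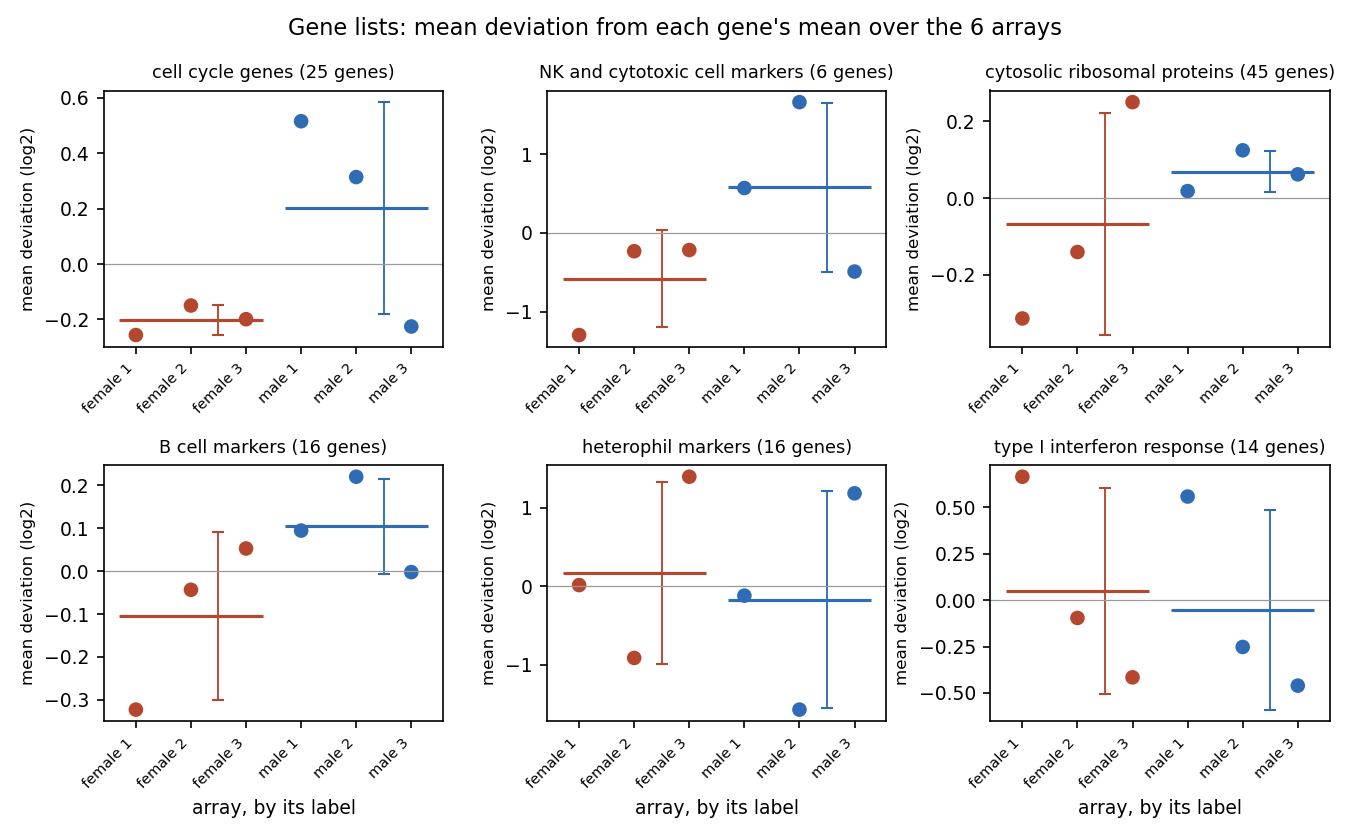
Mean log2 deviation of the genes of 6 lists from each gene's mean over the 6 arrays (y axis) in each array by its label (x axis); red points are libraries labelled female and blue points libraries labelled male, horizontal lines are group means and error bars 1 SD (n = 3). The cell cycle list is at 0.52 and 0.31 in the libraries labelled male 1 and 2 and at -0.23 in that labelled male 3, while the heterophil list is highest in both libraries numbered 3.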

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

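The alternatives without both libraries numbered 3 were chosen after seeing the data, by the HINTW and Z values of these libraries. All others were fixed before. Libraries are named by their labels. The Z shift kept its direction in each setting. Without the libraries labelled female 3 and male 3, 85 features passed instead of 0, 594 instead of 25 were 2-fold in all pairs (202 higher and 392 lower in the male-labelled libraries, against 15 and 10), 1 W gene instead of 0 passed, 8 lists instead of 4 passed (0 with an estimated correlation), the inflammatory list's median went from 0.10 to -0.20, that of sterol genes from 0.08 to -0.08 and that of W-linked gametologs from -0.04 to 0.17 log2, and the Z shift was 0.56 instead of 0.17 log2; fewer pairs are needed there, and the other causes were not tested beyond the label checks. Leaving out 1 library gave 0 to 2 passing features, and 2 only without that labelled male 1: RGS16 and ENSGALT00000045424 (limma adjusted p = 0.00597 each; RGS16 had 0.247 with all and up to 0.935 over its alternatives). It gave 47 to 117 features over 2-fold in all pairs left (47 without female 1, 61 without female 2, 117 without female 3, 60 without male 1, 63 without male 2 and 112 without male 3), which fewer pairs raise by construction; the balance turned to 45 higher and 72 lower without female 3 and to 44 and 68 without male 3. It gave a Z shift of 0.07 to 0.37 log2 (0.07 without female 1, 0.08 without female 2, 0.37 without female 3, 0.10 without male 1, 0.09 without male 2 and 0.37 without male 3), 0 W genes in each case, and 2 to 7 lists (2 without female 1, 7 without female 3 or male 3). Quantile normalization gave 1 passing feature, ENSGALT00000017478, and 2 lists (cell cycle and cytotoxic). The count over 2-fold in all pairs was 8 after normexp, 14 with probes well above background on all 6 arrays and 82 at 1.5-fold (37 higher and 45 lower); the stricter filter and the lower threshold act by construction, and for normexp the cause was not tested. With camera's estimated correlation the Z shift stayed at 0.17 log2 without passing (p = 0.401) and 0 lists passed, and with fry 0 lists passed. Over the other settings of scaling, filter and summary the Z shift was 0.16 to 0.21 log2. Scaling moved the median difference of all features between -0.05 and 0.03 log2. Of the 95 named genes, over all their alternatives, 1680 of 1705 values kept their sign and 25 did not. These 25 came from 13 genes, MBD2 among them, at most 0.44 log2 in size with all libraries. None passed on either side. Just 2 named genes came to pass, HINTW without both libraries numbered 3 and RGS16 without male 1.

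The labels do not say that replicate numbers pair the samples. Over all features, deviations of same-numbered libraries from their labelled group's mean correlated at 0.01, -0.11 and -0.21, and 0 of 6 libraries correlated best with their own number; both libraries numbered 3 stand apart from their labelled groups, and heterophil and interferon genes did follow the number. With the replicate block 0 features and 0 W genes passed, the Z shift was 0.17 log2 and 5 lists passed, the fifth being heterophil markers, lower in the male-labelled libraries; the 3 same-numbered pairs alone gave 63 features over 2-fold, as fewer pairs are needed. The 3 alternatives with slide (fixed block, random block, only slides with both labels) were not run, since slide and group cannot be told apart.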

Other observations

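All tests in this part were chosen only after the results they bear on were seen. Heterophil genes differed between libraries by replicate number, and alike in both labelled sexes. The defensins AvBD1, AvBD4, AvBD6, AvBD7 and DEFB4A, the cathelicidins CATH1 and CATH2, the chemotaxin LECT2 and the lysozyme LYG2, named after their values were seen, were 12.2- to 22.8-fold higher in the 2 libraries numbered 3 than in the 2 numbered 2. AvBD1 read 5.52 and 5.32 in the libraries labelled female 3 and male 3, 1.98 and 0.74 in those numbered 2, and 3.55 and 3.32 in those numbered 1. The other 7 heterophil list members moved less: MMP9 differed by 1.29, CSF3R by 0.68, EXFABP by 0.59, RNASE6 by 0.51, RSFR by 0.04, MMP7 by -0.19 and SERPINB10B by -0.44 log2.

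Type I interferon response genes also differed by replicate number, and 12 of the 14 measured were higher in both libraries numbered 1 than in both numbered 3, as were 20.2% of all features. The antiviral GTPase MX1 read 1.45 and 1.11 in the libraries labelled female 1 and male 1, and -1.29 and -1.48 in those numbered 3. IFI27L2 differed by 2.68, the RNA sensor IFIH1 by 1.46 and LY6E by 1.33 log2, while IFI6 was level at 0.01 log2; these too were chosen by their values.

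The sex-linked genes of the libraries labelled female 3 and male 3 ran against their labels. A weak array or another scaling factor that acts as 1 factor per array is argued against for Z genes, because it cancels in the Z minus autosomal value. That value, 0.28 log2 (0.2843) in the library labelled female 3, is the observation itself and not a separate measurement. A weak array that acts unevenly on genes was not tested. A mixture of RNA from both sexes is argued against for the library labelled female 3 only, and was not tested for that labelled male 3. The test used the 12 W probes over 2-fold higher in the libraries labelled female 1 and 2 than in male 1 and 2. They were 8 of HINTW, 3 of LOC100857579 and 1 of UBAP2L2. On them the library labelled female 3 lay a median of 620-fold below female 1 and 2. A share of 5% of female RNA would leave at most 20-fold. Values under the lowest one well above background were set to it; 9 of the 12 probes were over 20-fold, 6 of them well above background in that library. This test took the place of one on 29 features that were well above background in the libraries labelled female 1 and 2, not in male 1 and 2 and at least 4 log2 lower there. The median of those is 15.3-fold with the same limit, and 26 of the 29 lay at or under it in the library labelled female 3. This fold is thus a lower bound and does not decide whether the drop passed 20-fold. On 26 of the 29 both libraries numbered 3 lay on the other side of the midpoint, and on 2 neither did. An exchange of the 2 libraries may account for the W genes: all 12 of these W probes, which stand for only 3 genes, 2 of them related, had both libraries numbered 3 on the other side, while the other 23 kept W probes did not separate the first 2 libraries of each sex by 2-fold; of 145 Z genes that separated the first 2 libraries of each sex, 107 (73.8%) had both libraries numbered 3 on the other side, just under the 75% set for that test, and the W test was added after it. Whether birds, tubes, array positions or files would have been exchanged, and whether sex itself differed from the record, stays open and untested.

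RGS16 and the other features over 2-fold in all 9 pairs were picked because they separate the labels, so their course in the libraries labelled female 3 and male 3 was fixed by that choice. RGS16 read 2.78 log2 in the library labelled female 3 and -4.68 in that labelled male 3. It thus went with the labels and did not follow the HINTW and Z values of these libraries. Slide or another batch shared by a labelled group cannot be told apart from the label, because the number of slides holding both labels was 0. A difference at 1 RGS16 probe, such as a sequence variant, could account for part of the gap, since the other probe differed by only -0.99 log2; that value is neither near 0 nor near the -6.53 of the first probe, so this stays open.

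The differences of heterophil and interferon genes by replicate number may come from the samples or from array position, since number and position on the slide coincide. A shift of all features with position is argued against for the heterophil genes. Before scaling, 9.83% of all features were higher in both libraries numbered 3 than in both numbered 2, against 56.3% of heterophil genes. Chance gives 16.7%. The order of the interferon genes was not examined before scaling, so it is not covered. An effect of position on some genes stays open. A larger heterophil share in the samples numbered 3, in the blood or left by the density gradient, stays open, because only 9 of 16 heterophil markers showed that order. Chance matching stays open too: 4 of 20 lists matched best by replicate number, where 1 in 6 would by chance. No biological explanation that the design names was tested for it.

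The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. With the labelled sexes 0 genes passed, and the highest of the other splits gave 546. For features over 2-fold in all 9 pairs the values were 25 and 196, for W genes 0 and 2, and for lists 4 and 7. Counting the labelled split, 4 of the 10 splits gave at least 25 such features and 7 gave at least 4 lists. The labelled split was thus not unusual in either count. Where the labelled split gives 0, every split is as large by construction. The split with 546 genes places the library labelled male 3 with those labelled female 1 and 2. Each of the other splits gave 0 to 2 genes. The split with 546 is also the one that groups the libraries by their HINTW and Z values, with a Z shift of 0.55 log2. A count of 546 points to a structure of the samples other than the labels. The genes of this split are not listed, since that grouping comes from the data.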
